A study of Rattus norvegicus with 24 samples.

How the data were processed

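Poly-A RNA of amygdala and dorsal raphe from 60-day-old rats was sequenced in 24 libraries, 6 for each pairing of a bred line (high-responder or low-responder) with a brain region. Per the labels' protocols, RNA was extracted with a Qiagen miRNeasy kit and made into poly-A libraries. Per the submitters' processing notes, Trim Galore, STAR and the rat genome build rn6 were used. Their versions, the counting program, the annotation release, the strand setting and the treatment of reads that match several genes were not given in the sources used here. The deposited values are raw counts of reads per gene, as whole numbers, with 1 table per library. Each table lists the same 32662 Ensembl gene IDs in the same order and has 0 lines that name no gene. At least 1 count was present in any library for 24750 of them. Near-identical gene copies, overlapping genes and antisense partners could not be told apart from these tables, so the value of a single ID is uncertain where it shares reads with another.

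The tables do not pair the IDs with gene symbols, and the reference table used here, a RefSeq gene table of the assembly GRCr8, matched 0 of them. Genes are therefore given by ID. The gene lists and cell type markers chosen before the data were examined could not be applied, their tests were not run, and checks of GC content and gene length were void because no ID had a value. The rule for named genes asked for a symbol, an adjusted p past the threshold, a mean of at least 1 CPM (10 CPM between regions) in the higher group and complete separation of the libraries of the 2 groups (not asked for the strain by region test or for the mean of the 2 strain differences), ranked by log2 fold change. Without symbols it was applied to the IDs, and at most 2 that were higher and 2 that were lower are printed per comparison.

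Libraries were assigned to groups by the line and region in their labels. No label says whether the 6 libraries of a group came from 6 animals, or whether equal numbers in the 2 regions stand for the same rat, so p-values measure the spread between these libraries, which may be partly technical. Library totals ranged from 9232983 to 20194601 counts, and 18455 to 19821 genes had at least 1 count per library. Within each group every pair of libraries differed by more than counting noise (chi-square per degree of freedom of at least 3.46 in the closest pair, over genes with 10 or more counts in the pair), so none was treated as a duplicate. Sequencing reads without molecular identifiers are not independent molecules, so the floors and intervals given here cover counting error only. A gene with 0 counts in a group was given a floor of 3 counts over the group.

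Counts were tested with edgeR 4.0.16 in R 4.3.3 by glmQLFit and glmQLFTest, after filterByExpr on the groups fitted and TMM normalization, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors are the log2 fold change divided by the square root of the F statistic. The strain comparison was fitted in each region on its 12 libraries. The strain by region comparison (the high minus low-responder difference in amygdala minus that in dorsal raphe) and the region comparison (the mean of the 2 amygdala groups minus the mean of the 2 dorsal raphe groups) were fitted on all 24 libraries as 4 groups. Positive log2 values are higher in high-responder rats or in amygdala. CPM values (counts scaled to a common library total) printed per group were computed from the deposited counts with TMM factors over all 24 libraries and are mean ± SD. Library totals were compared with a two-sided exact permutation test. Principal components were computed from log2 CPM with a prior count of 2.

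Each comparison was tested on simulated counts drawn from the means and library sizes of the real genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At a 2-fold change, 92.5% of the changed genes were recovered in the amygdala strain comparison (14265 genes), 74.6% in the dorsal raphe (14390 genes), 68.7% in the strain by region comparison and 94.0% between regions (14977 genes each). At 1.5-fold the shares were 62.7%, 49.3%, 29.9% and 67.2%, and at 4-fold 98.5%, 95.5%, 92.4% and 100%. False calls were 2.87%, 2.01%, 3.79% and 7.94% of the calls made. The simulated libraries held no axis of variation within groups such as the dorsal raphe libraries showed. They also held many more changed genes than the strain and strain by region comparisons called. Simulated calls were 174 in the amygdala, 149 in the dorsal raphe and 132 for strain by region, against 3, 9 and 1 in the real data. With fewer calls the adjusted p asks for a smaller unadjusted p, so recovery at the real threshold would be lower. That recovery was not simulated.

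Alternatives chosen before the data were examined were RLE size factors, library size only, no filter beyond 1 count, at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, a test against a fold change of 1.2 (glmTreat), all 24 libraries in the fit of 1 region, the replicate number as a block, and leaving out each library. After the data were seen, library numbers in the file headers were used as a batch. Within each group the libraries after the first break in consecutive numbers are called later and the others earlier. Alternatives with a term for later libraries, with earlier or later libraries alone, without the amygdala libraries numbered 3, and without 34 neighbouring table lines that held many of the highest counts were then added, as was the mean of the 2 strain differences over both regions. All library numbers of the low-responder rats are lower than all those of the high-responder rats, so strain and any batch that follows the whole order of the numbers cannot be told apart.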

Results

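Gene expression was measured by poly-A RNA sequencing in the amygdala and the dorsal raphe of 2 rat lines that were bred for opposite responses to a new environment. High-responder rats explore such an environment more than low-responder rats. The amygdala is a forebrain region involved in emotional behaviour, and the dorsal raphe is a midbrain nucleus that holds many of the serotonin neurons of the brain. There were 6 libraries for each line and region, 24 in all. The mean total was 12530688 ± 3813862 counts in high-responder amygdala, 13766548 ± 4294489 in high-responder dorsal raphe, 12588302 ± 927238 in low-responder amygdala and 11732226 ± 1469612 in low-responder dorsal raphe (SD, n = 6 each). Totals did not differ detectably between the lines in the amygdala (two-sided exact permutation p = 0.994, n = 6 per line) or in the dorsal raphe (exact p = 0.355).

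Region was the main axis of the data. The first principal component, with 65.7% of the variance, placed all 12 amygdala libraries on one side and all 12 dorsal raphe libraries on the other. The second, with 11.4%, spread the dorsal raphe libraries of both lines, from -38.53 in low-responder library 3 to 58.71 in low-responder library 5. High-responder dorsal raphe libraries 4 and 5 lay at 43.02 and 37.36. Libraries with later library numbers lay toward the positive end: the 5 later dorsal raphe libraries ranged from -1.15 to 58.71 and the 7 earlier ones from -38.53 to -0.74. A comparison of later with earlier dorsal raphe libraries within the lines, made after this was seen, called 6919 of 14390 genes with edgeR's quasi-likelihood test, 3491 higher and 3428 lower in later libraries. The same comparison in the amygdala called 0 of 14265 genes with edgeR, with 545 genes at an unadjusted p under 0.05. No other tool was run on it.

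**Figure D1:**
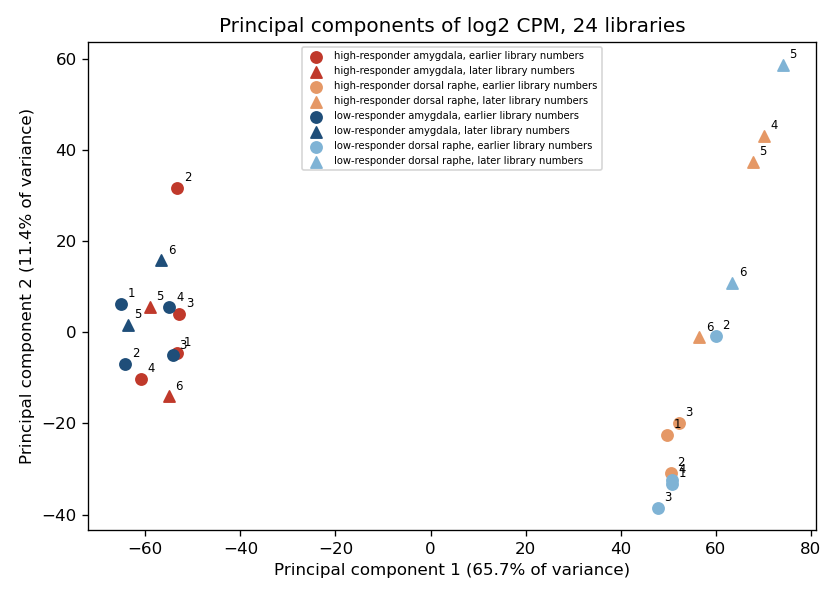
Each point is 1 of the 24 libraries, placed by its scores on principal components 1 (65.7% of variance) and 2 (11.4%) of log2 CPM, coloured by group, numbered by replicate, with triangles for later library numbers. The regions part along component 1, and the dorsal raphe libraries of both lines spread along component 2 from -38.53 to 58.71.

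The amygdala of the 2 lines was compared to ask which genes differ between them. With 1 line bred for each response, a difference between the lines cannot be tied to the response itself. ENSRNOG00000017412 was lower in high-responder amygdala, at 0.195 ± 0.116 CPM against 2.21 ± 0.624 CPM in low-responder amygdala (SD, n = 6 each), with a log2 fold change of -3.49 (SE 0.33, edgeR adjusted p = 0.000462). ENSRNOG00000025728 was also lower, at 1.15 ± 0.240 against 2.91 ± 0.639 CPM, with a log2 fold change of -1.32 (SE 0.20, edgeR adjusted p = 0.0495). For both IDs all 6 high-responder libraries lay below all 6 low-responder libraries. ENSRNOG00000017412 rested on 1 to 4 counts in each high-responder library and on 18 to 40 in each low-responder library.

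In all, 3 of 14265 genes passed the threshold in the amygdala, 0 higher and 3 lower in high-responder rats. An unadjusted p under 0.05 was found for 1189 genes (8.34%, against 5% with no difference). Some other splits of the 12 libraries into 2 groups of 6 gave more, such as 2352, 2315 and 2137 genes. A count of this size is therefore not particular to the lines. All 6 libraries of one line lay above all 6 of the other for 102 genes (0.715%), against 0.217% by chance. That chance share is an average over all splits, and genes are not independent. The 102 genes were not compared with single splits, so this count is not shown to be particular to the lines either. Within batches, the 4 earlier libraries per line called 0 genes with edgeR (705 at an unadjusted p under 0.05), with a log2 fold change of -3.28 for ENSRNOG00000017412 and -1.36 for ENSRNOG00000025728. The 2 later libraries per line called 61 genes, 1 of them among the 3, with log2 fold changes of -3.84 and -1.27 for these 2 IDs. The number of calls depended on the tool and the libraries: DESeq2 called 82 genes and limma voom with quality weights 246, each with the 3 among them, and leaving aside the libraries numbered 3 of both lines gave 10. Without high-responder library 2 the count was 27, without low-responder library 3 it was 13, and it was 1 without any one of high-responder libraries 1, 4, 5 and 6 or low-responder libraries 1 and 2, while ENSRNOG00000017412 passed in each of these. In the earlier libraries alone ENSRNOG00000017412 did not pass (edgeR adjusted p = 0.0739). The call of ENSRNOG00000025728 ended in the earlier (edgeR adjusted p = 0.242) and in the later libraries alone (0.273), with RLE (0.0536), library size only (0.0534), no low count filter (0.0756) and a fold of 1.2 (0.169), without the libraries numbered 3 (0.0591), without 34 abundant table lines (0.0548) and in 9 of 12 fits that left out 1 library, with a log2 fold change of -1.38 to -1.24 in these 9.

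The same question was asked of the dorsal raphe. ENSRNOG00000061943 was higher in high-responder rats, at 7.63 ± 4.25 against 0.113 ± 0.0996 CPM (SD, n = 6 each), with a log2 fold change of 5.94 (SE 0.59, edgeR adjusted p = 0.00231). It had 0 to 3 counts in each low-responder library and 37 to 235 in each high-responder library. ENSRNOG00000054553 was higher as well, at 2.36 ± 0.614 against 0.390 ± 0.255 CPM, with a log2 fold change of 2.56 (SE 0.40, edgeR adjusted p = 0.0395). ENSRNOG00000028041 was lower in high-responder rats, at 1.26 ± 0.304 against 27.95 ± 26.2 CPM, with a log2 fold change of -4.48 (SE 0.52, edgeR adjusted p = 0.00569). The wide spread of its low-responder values came with 1 library, number 5, at 80.08 CPM. The other 5 lay between 12.1 and 26.9 CPM, all above the highest high-responder value of 1.78 CPM, and without library 5 the log2 fold change was -3.80 and still passed (edgeR adjusted p = 4.18e-05). ENSRNOG00000054418 was lower too, at 0.695 ± 0.349 against 7.35 ± 3.80 CPM, with a log2 fold change of -3.38 (SE 0.47, edgeR adjusted p = 0.0298).

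In all, 9 of 14390 genes passed the threshold in the dorsal raphe, 5 higher and 4 lower in high-responder rats, and all 9 had complete separation of the 2 lines. An unadjusted p under 0.05 was found for 726 genes (5.05%), and 78 genes (0.542%) were completely separated, against 0.217% by chance. The 0.217% is an average over all splits, and the 78 genes were not compared with single splits. Within batches, the earlier libraries (3 high-responder and 4 low-responder) called 16 genes, of which 6 were among the 9. The later libraries (3 high-responder and 2 low-responder) called 0 with edgeR, with 237 at an unadjusted p under 0.05. In the earlier and the later libraries the log2 fold change was 5.54 and 5.81 for ENSRNOG00000061943, 2.58 and 2.28 for ENSRNOG00000054553, -3.69 and -5.33 for ENSRNOG00000028041 and -3.41 and -2.57 for ENSRNOG00000054418. With a term for later libraries the count was 12. DESeq2 called 39 genes and limma voom 26, and a test against a fold change of 1.2 called 4. The count was 3 without any one of high-responder libraries 1, 2, 3, 5 and 6 or low-responder libraries 1, 2 and 4, and 5 without low-responder library 3, and ENSRNOG00000061943 and ENSRNOG00000028041 passed in each of these. The call of ENSRNOG00000054553 ended with limma voom (adjusted p = 0.0528) and against a fold of 1.2 (edgeR adjusted p = 0.0733), and in the earlier (edgeR adjusted p = 0.228) and the later libraries alone (0.9995). It and ENSRNOG00000054418 each lost the call in 10 of 12 fits that left out 1 library, with log2 fold changes of 2.47 to 2.72 and -3.55 to -3.19 in those 10.

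**Figure D2:**
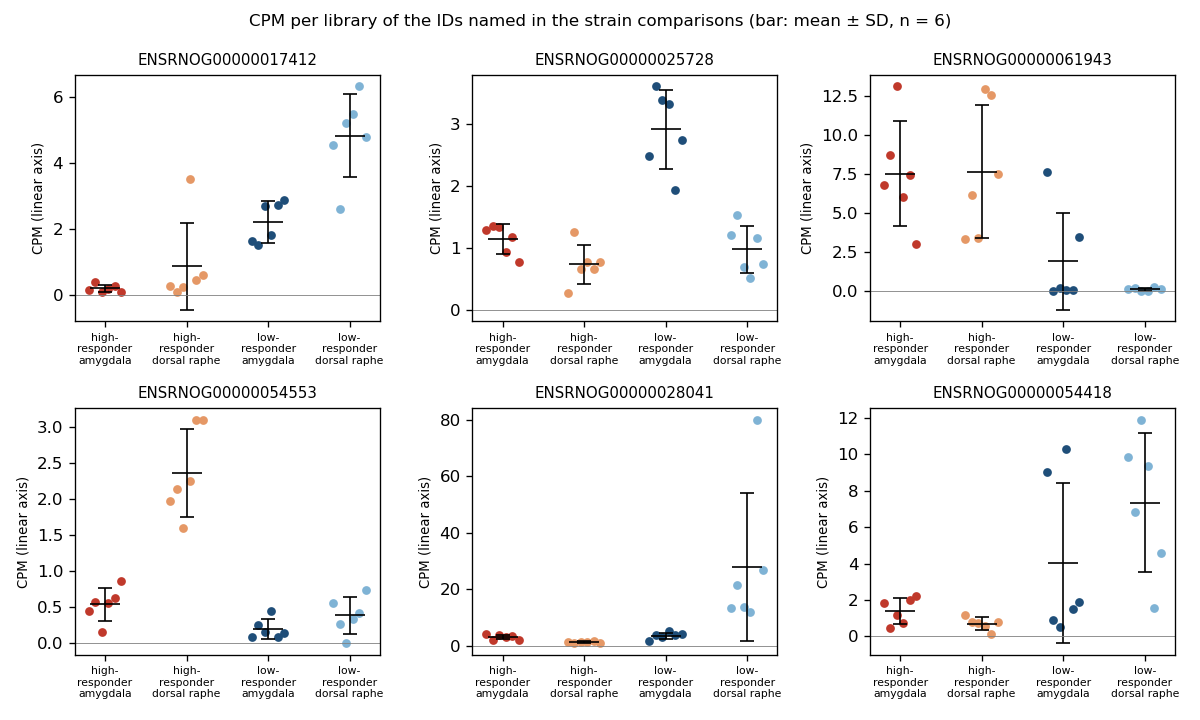
Each panel shows 1 ID named in the strain comparisons, with CPM on a linear axis, 1 point per library, the 4 groups along the horizontal axis, and the mean with its SD (n = 6) in black. ENSRNOG00000017412 averaged 0.195 CPM in high-responder and 2.21 CPM in low-responder amygdala, and ENSRNOG00000061943 averaged 7.63 CPM in high-responder and 0.113 CPM in low-responder dorsal raphe.

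Whether the strain difference itself differed between regions was tested on all 24 libraries. Of 14977 genes, 1 passed the threshold, ENSRNOG00000028041, with a difference of 4.28 on the log2 scale (SE 0.58, edgeR adjusted p = 0.00195). In the amygdala it stood at 3.12 ± 0.845 CPM in high-responder and 3.63 ± 1.09 CPM in low-responder rats (SD, n = 6 each), a log2 fold change of -0.20 (SE 0.23), while in the dorsal raphe the fold change was -4.48. Without low-responder dorsal raphe library 5 the difference was 3.60 and still passed. The other genes had adjusted p values of at least 0.9999, and 458 genes had an unadjusted p under 0.05. In earlier libraries alone 2 genes passed, this one among them at 3.62. In later libraries alone edgeR called 0 (534 at an unadjusted p under 0.05), with 4.84 for this ID. DESeq2 called 1 gene and limma voom 2 over all libraries.

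The 2 strain comparisons share no library, but the labels do not say whether the same rats gave both regions. Of 13820 genes tested in both regions, 0 passed in both with edgeR, DESeq2 called 1 in both and limma voom 3. At an unadjusted p under 0.01, 299 genes in the amygdala and 180 in the dorsal raphe passed, and 17 passed in both, against 3.89 if the lists were independent. All 17 had the same sign in both regions. Rats shared by the regions, or a batch that follows the order of the library numbers, could also give such an overlap. It was not compared with other splits. Of the 9 genes called in the dorsal raphe, 8 were tested in the amygdala, all 8 with the same sign, and 7 passed there when adjusted over those 8 alone. Among these 7, ENSRNOG00000061943 and ENSRNOG00000054418 were uneven in low-responder amygdala. ENSRNOG00000054418 stood at 9.05 and 10.28 CPM in libraries 1 and 4. Its other low-responder values, 0.54 to 1.87 CPM, lay within the high-responder range of 0.482 to 2.21 CPM. ENSRNOG00000061943 stood at 7.60 and 3.46 CPM in libraries 1 and 6, within its high-responder range of 2.98 to 13.1 CPM. The rest of the 7 are not given by library here. Of the 3 called in the amygdala, 2 were tested in the dorsal raphe, 1 with the same sign, and 1 passed when adjusted over those 2 alone. That one was ENSRNOG00000017412, with a log2 fold change of -2.38 (SE 0.62) in the dorsal raphe, where high-responder library 4 stood at 3.51 CPM and the other 5 high-responder libraries at or below 0.603 CPM. Across genes, which are not independent replicates, the log2 fold changes of the 2 regions correlated with Pearson's r of 0.282 (jackknife SE over libraries 0.131) and Spearman's rho of 0.272. Within batches r was 0.277 in earlier and 0.180 in later libraries. With no low count filter it was 0.062.

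**Figure D3:**
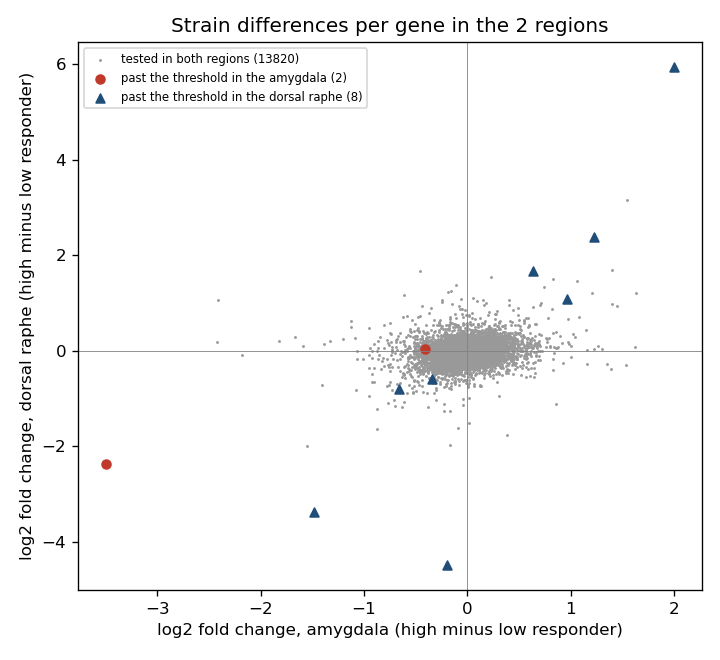
Each point is 1 of the 13820 genes tested in both regions, with its log2 fold change (high minus low responder) in the amygdala on the horizontal axis and in the dorsal raphe on the vertical axis. The 2 genes past the threshold in the amygdala are red circles and the 8 past it in the dorsal raphe are blue triangles, all 8 with the same sign in both regions.

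The 2 regions were compared over both lines. ENSRNOG00000051264 had 1889 counts over the 12 amygdala libraries, 12.5 ± 2.28 CPM (SD, n = 12), and 0 counts over the 12 dorsal raphe libraries, which with a floor of 3 counts over the group made it at least 642-fold higher in the amygdala. ENSRNOG00000047891 stood at 118.7 ± 9.01 CPM in the amygdala and 0.117 ± 0.125 CPM in the dorsal raphe, a log2 fold change of 9.84 (SE 0.19, edgeR adjusted p = 6.9e-23). ENSRNOG00000003476 was higher in the dorsal raphe, at 399 ± 143.5 against 0.399 ± 0.381 CPM, a log2 fold change of -9.99 (SE 0.37, edgeR adjusted p = 2.58e-17). ENSRNOG00000017856 was higher there too, at 23.5 ± 8.54 CPM against 4 counts over the 12 amygdala libraries, a ratio of 888 with a 95% counting interval of 347 to 3261. Both of these IDs were low in high-responder dorsal raphe library 1, at 58.1 and 4.13 CPM, against at least 303.7 and 14.8 CPM in the other 11 dorsal raphe libraries.

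In all, 9851 of 14977 genes (65.8%) passed the threshold between regions, 4764 higher in the amygdala and 5087 higher in the dorsal raphe. More than 2-fold differences were found for 1259 and 1323 genes, and more than 4-fold ones for 452 and 398. The median size of a called log2 fold change was 0.58. All 12 libraries of one region lay above all 12 of the other for 3334 genes (22.3%), against 7.4e-05% by chance. Earlier libraries alone called 8970 genes and later ones alone 9251. Against a fold change of 1.2, 6439 genes passed.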

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

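Chosen only after their results were seen, or related ones, were the tests of the library numbers against chance, against a shared batch and against the region difference, the test of the abundant lines in the amygdala libraries numbered 3, and the counts of splits except that between regions, and, in the last paragraph, the choice of genes without the libraries tested and the test of their places outside the high-responder range. The fit with a term for later libraries was also added after the data were seen. The other tests of this part were chosen before.

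Of 60 groups of 6 values examined, 11 held a library far from the other 5, where a rate of 1 in 20 gives 3. Some measures overlap, such as the total and the detected genes of 1 library. The 11 are therefore not independent, and their excess over chance was not tested. High-responder amygdala library 1 had the largest total of its group, 20194601 counts against at most 12243679 in the others, and 19633 detected genes. In low-responder amygdala library 3 the 10 most counted genes took 3.80% of the counts and 34 neighbouring table lines, which hold 8 of the 10 most counted genes of the series, took 1.62%, and ENSRNOG00000047891 stood at 140 CPM against at most 122 CPM in the others. In low-responder dorsal raphe library 5 those 2 shares were 15.18% and 14.68%, and ENSRNOG00000028041 stood at 80.08 CPM. ENSRNOG00000017412 stood at 3.51 CPM in high-responder dorsal raphe library 4, where the others reached 0.603 CPM. ENSRNOG00000003476 stood at 1.51 CPM in low-responder amygdala library 2, and ENSRNOG00000057895 at 1.70 CPM in low-responder dorsal raphe library 6.

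The strain difference of ENSRNOG00000028041 differed between regions by 4.28 on the log2 scale in the test of that difference. Over 100 splits of the libraries within regions, the real one included, 7 gave at least 1 such gene, so chance is not excluded for the count of 1 gene. The highest other split gave 4929, and a split with so many more calls than the real one points to a structure of the libraries. That split put all 5 later dorsal raphe libraries on one side. With a term for later libraries the difference was 4.27 (edgeR adjusted p = 5.25e-05). Of 100 splits made within the earlier and within the later libraries of each region, 6 gave at least 1 gene (highest other 4), and with the term in the fit 5 did (highest other 18), the real one included, so chance is not excluded there either.

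The dorsal raphe libraries parted by library number, with 6919 genes called between later and earlier libraries. Of 100 splits with the same numbers per line, 1, the real one, gave as many (the highest other gave 4209), so chance is argued against. Depth as the whole source is argued against, since 91.0% of the genes were called again with the same sign after every library was thinned to the smallest total, and a few dominant genes are too, since 96.8% of the remaining genes were called again without the 34 lines and the 100 most counted genes. A batch made up of the later libraries of both regions, with a like effect in each, is argued against. Between later and earlier amygdala libraries edgeR called 0 genes (545 at an unadjusted p under 0.05), and no other tool was run. Later was set in each group by its own break in the numbers, so the later libraries of the 2 regions need not be 1 batch. A batch that took in other amygdala libraries was not tested. A different mix of tissue in the dissected piece stays open and cannot be told apart from a batch among the dorsal raphe libraries. Across genes the later minus earlier change correlated with the dorsal raphe minus amygdala difference at r = 0.20, between the bounds set for either answer. No biological explanation was tested.

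The amygdala libraries numbered 3 of both lines stood apart, with 3.00% and 1.62% of their counts in the 34 lines where the other amygdala libraries had 5.97% to 8.11%. Loss of these lines alone is argued against, since without them the deviations of the 2 libraries from their groups still correlated at r = 0.57 across genes, with 99 of 14962 genes more than 2-fold apart in both in the same direction. A mix with tissue along the axis from dorsal raphe to amygdala is argued against too, as the larger of their 2 correlations with that axis was 0.09. That axis does not cover a mix with other tissue, which was not tested. A shared preparation of the libraries numbered 3 was not tested, and neither was a biological explanation.

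ENSRNOG00000061943, higher in all 6 high-responder dorsal raphe libraries, was uneven in low-responder amygdala, with 7.60 CPM (89 counts) in library 1, 3.46 CPM (48 counts) in library 6 and at most 0.154 CPM in the other 4. Wrong labels on libraries 1 and 6 were tested on the other genes that differed between the lines on average, with positions from 0 at the low-responder to 1 at the high-responder mean. Over 38 genes chosen with both libraries in the fit their median positions were 0.08 and -0.06. Over 33 genes chosen without both the positions were 0.42 and 0.25, and over the 5 fits that left out each library with 1 other of its group they ranged from 0.16 to 0.42 for library 1 and from 0.24 to 0.50 for library 6. None lay above 0.5, but the highest of each lay within the SD of 0.15 of that bound. A wrong label or a mixed sample thus cannot be told apart from the spread of the group. The high-responder mean, and the ranges used below, include high-responder library 2, which itself lay toward the low-responder mean. Among the named IDs chosen with both libraries in the fit, libraries 1 and 6 both ran with their labels for 3: ENSRNOG00000017412 stood at 1.62 and 2.88 CPM (0.079 to 0.386 CPM in high-responder amygdala), ENSRNOG00000025728 at 2.48 and 2.74 CPM (at most 1.35 CPM) and ENSRNOG00000057895 at 0 and 0.0721 CPM, below all 6 high-responder libraries. ENSRNOG00000054418 stood at 9.05 CPM in library 1, above all 6, but at 1.87 CPM in library 6, within the high-responder range of 0.482 to 2.21 CPM. Another test used 15 genes chosen without both that parted the other 4 low-responder from the 6 high-responder libraries. Library 1 lay outside the high-responder range on the low-responder side for 7 (46.67%) and library 6 for 8 (53.33%). About 14.29% is expected of a high-responder library if the genes were not chosen by these ranges. They were chosen so, which can raise the expected share by an amount that was not computed. ENSRNOG00000017412 was 1 of the 15. Only the share of library 6 reached the bound of 50% set for correct labels, and the share that exchanged labels would give is not known. Exchanged labels thus stay open, and this test does not decide between them and correct labels. An inherited difference that is not fixed in the low-responder line stays open as well and was not tested.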

How the results depend on the processing

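The alternatives built on library numbers, on the libraries numbered 3 and on the 34 abundant lines, and all those of the mean strain comparison, were chosen after the data were seen. The cause of a change in a count was not tested. Earlier or later libraries alone are fewer, but counts in them rose as well as fell. In the amygdala, 3 strain genes became 1 with RLE, with library size only, with no low count filter, against a fold of 1.2 and without the 34 lines, 82 with DESeq2, 246 with voom, 6 with all 24 libraries in the fit, 10 without the libraries numbered 3, 0 in earlier and 61 in later libraries. In the dorsal raphe, 9 became 39 with DESeq2, 26 with voom, 4 against a fold of 1.2, 16 in earlier and 0 in later libraries. The interaction count of 1 became 2 with voom and in earlier libraries and 0 in later ones. The region count of 9851 became 6439 against a fold of 1.2. The mean strain count of 39 became 163 with DESeq2, 529 with voom, 15 against a fold of 1.2, 93 with a term for later libraries, 17 in earlier and 1 in later libraries. Genes called in both regions rose from 0 to 1 with DESeq2 and 3 with voom, and the correlation of fold changes fell from 0.282 to 0.062 with no filter. No named ID changed sign under any alternative. Leaving out 1 library gave 1 to 27 amygdala genes, 3 to 12 dorsal raphe genes, 1 interaction gene each time, 9668 to 10107 region genes, 29 to 75 mean strain genes (75 without high-responder amygdala library 2, 74 without low-responder dorsal raphe library 5), 0 to 1 shared genes and a correlation of 0.185 to 0.319. ENSRNOG00000025728 lost its call in 9 of 12 such fits (adjusted p up to 0.175), ENSRNOG00000054418 and ENSRNOG00000054553 in 10 of 12 each (up to 0.122 and 0.169). By the rule that every pair must correlate above 0.1, equal replicate numbers did not pair the libraries, though a pairing of some is not excluded: between regions the deviations of equal numbers correlated from -0.30 to 0.19 in high-responder and from -0.08 to 0.14 in low-responder rats, and between lines from -0.33 to 0.58 in the amygdala and from -0.52 to 0.65 in the dorsal raphe, where 1, 0, 2 and 2 of 6 libraries correlated best with their own number. With the replicate block the counts were 3 in the amygdala (1 of them among the 3 without it), 5 in the dorsal raphe, 1 for the interaction and 9424 between regions. With it ENSRNOG00000025728 (log2 -1.32, adjusted p = 0.114) and ENSRNOG00000054553 (2.63, 0.184) did not pass, and the other named IDs of the 4 planned comparisons did. Gene list tests could not be run in any setting, as 0 IDs had a symbol. In simulated data a 1.5-fold strain difference was recovered for 62.7% of changed genes in the amygdala and 49.3% in the dorsal raphe. Those data held more changed genes than were called here, so the shares at the real threshold would be lower. Differences of this size and smaller were thus often not detectable.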

Other observations

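The mean strain comparison with its alternatives, the counts of splits other than that between regions, the positions of libraries between the lines and the tests of both hypotheses were chosen only after the data were seen. The count of splits between regions and the strain counts of single regions with 1 library left out were planned before.

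Over both regions together, 39 of 14977 genes differed between the lines on average, 18 higher and 21 lower in high-responder rats, with edgeR's quasi-likelihood test on all 24 libraries. This fit took the 24 libraries as independent, and it was not run with the replicate block. If the same rats gave both regions, its p-values may be too small. With library size only as the scaling the count was 45, with 29 higher and 16 lower. ENSRNOG00000061943 was higher, with a mean log2 fold change of 3.96 (SE 0.63, edgeR adjusted p = 0.00308), and so was ENSRNOG00000057895 at 2.64 (SE 0.50, edgeR adjusted p = 0.0136), which averaged 0.995 ± 0.596 CPM in high-responder and 0.108 ± 0.0698 CPM in low-responder amygdala and 1.38 ± 0.755 and 0.352 ± 0.663 CPM in dorsal raphe (SD, n = 6 each). ENSRNOG00000017412 was lower at -2.93 (SE 0.40, edgeR adjusted p = 0.000858) and ENSRNOG00000054418 at -2.43 (SE 0.44, edgeR adjusted p = 0.0104). Earlier libraries alone called 17 genes and later ones alone 1, with log2 fold changes of -3.85 and -2.78 for ENSRNOG00000017412, 3.86 and 3.65 for ENSRNOG00000061943, 3.67 and 1.76 for ENSRNOG00000057895 and -2.79 and -1.12 for ENSRNOG00000054418. Of the 17 genes 11 were among the 39, and the 1 gene of the later libraries was not. In earlier libraries alone ENSRNOG00000061943 (edgeR adjusted p = 0.161) and ENSRNOG00000054418 (0.0602) did not pass, and in later ones alone none of the 4 IDs did. Single libraries moved 3 of the 4 by more than 1.5-fold: without high-responder dorsal raphe library 4 ENSRNOG00000017412 was at -3.70, without low-responder dorsal raphe library 6 ENSRNOG00000057895 was at 3.54, and without low-responder amygdala library 1 ENSRNOG00000061943 was at 4.58, and each still passed.

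Other splits of the libraries gave the following, where fewer than 5 of 100 splits were taken to argue against chance. The counts were not adjusted for the number of such tests. For the 3 amygdala strain genes, 2 of 100 splits gave as many, the real one included, which argues against chance without excluding it. The highest other split gave 16 and put all 4 later libraries on one side. For the 9 dorsal raphe strain genes, 4 of 100 splits gave as many, the real one included. This lies so near the bound of 5 that chance is not excluded. The highest others gave 6929, 4838 and 2748 and put 5, 4 and 4 of the 5 later libraries on one side. Their sides also part along principal component 2, with means of 24.7 and -29.6, 21.1 and -26.0, and 19.3 and -24.2, and the library number was not told apart from that axis. The real split has 3 later high-responder and 2 later low-responder libraries, and with a term for later libraries 12 genes were called. For the 39 genes of the mean strain comparison, 3 of 100 splits gave as many (highest other 3287). These splits were drawn in each region separately, so they do not keep any rats shared by the regions together. The count argues against chance, without excluding it, only if no rats gave both regions. For the 9851 region genes only the real split, 1 of 100, gave as many (highest other 6911), and chance is excluded. The correlation of the strain fold changes between regions, 0.282, was reached by 5 of 100 splits (highest other 0.353), and chance is not excluded.

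A hypothesis was that stretches of the genome differ between the lines, as fixed by breeding, so that genes near each other in the table differ together. The 100 genes with the smallest p in the mean strain comparison held 7 neighbouring pairs in table order, and 5 of 100 splits held as many, the real one included (highest other 10). The test did not decide it, in part because table order was not checked against genome position.

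A second hypothesis was that equal numbers in the 2 regions mark the same rat. Over genes with a gap of more than 1.5 (log2 CPM with 0.5 added) between high and low libraries in both regions, equal numbers matched no better than most of the 720 pairings in high-responder rats (12 genes, exact p = 0.704). In low-responder rats they matched better (13 genes, exact p = 0.0417). The test did not decide the hypothesis, since a large p over 12 genes does not show that a match is absent. The low-responder value, 1 of 2 tests and unadjusted, stays unexplained.

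High-responder dorsal raphe library 1 had the lowest values of both IDs named as higher in the dorsal raphe, 58.1 CPM of ENSRNOG00000003476 and 4.13 CPM of ENSRNOG00000017856. Without it, 3 strain genes were called in the dorsal raphe.

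High-responder amygdala library 2 lay far toward the low-responder mean. When genes that differ between the lines on average were chosen without it and 1 other high-responder amygdala library, over 39 to 54 genes, its median position was 0.49 to 0.68, where 0 is the mean of its own line and 1 that of the other. The other 5 high-responder amygdala libraries lay between -0.07 and 0.23, and the low-responder ones, measured the same way, between -0.19 and 0.50. The 4 IDs named for this comparison did not all go one way in it. ENSRNOG00000057895 stood at 0.0964 CPM (1 count), within the low-responder range of 0 to 0.176 CPM and below the other 5 high-responder amygdala libraries, at 0.673 to 1.74 CPM. ENSRNOG00000061943 at 8.68 CPM, ENSRNOG00000017412 at 0.386 CPM and ENSRNOG00000054418 at 0.482 CPM lay outside the low-responder range, on the side of its own line. Without it 27 amygdala genes and 75 genes of the mean strain comparison were called. No explanation was tested.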
